A study of Mus musculus with 15 samples.

How the data were processed

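RNA sequencing was carried out on polyadenylated RNA of primary astrocytes from mouse brain, in 15 libraries. Per the labels, RNA was extracted with TRIzol, libraries were made with the VAHTS Universal V6 kit, and sequencing and the first processing were done by OE Biotech. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here. For each library the authors deposited raw counts per gene symbol for 25748 symbols, and FPKM, that is counts scaled to gene length and to the total of counted fragments. Every deposited FPKM value equalled count divided by gene length and total count, with 1 length per gene, to a relative deviation of at most 7.22e-10. In each deposited FPKM file, 37 rows carried damaged symbols and were left out. The count files held these genes intact, and all main results rest on the counts.

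The libraries form 3 groups of 5. The control group was untreated. The LPS group, labelled SCI by the submitters, received 1 µg/mL lipopolysaccharide for 6 to 8 h. The Rg1 plus LPS group received 80 µM ginsenoside Rg1 for 12 h and then the same dose of lipopolysaccharide for 6 to 8 h. The treatment field of the third group runs from Rg1 to Rg5 over its 5 libraries, while the sample titles and the design text give 5 replicates of Rg1. The titles and the design text were followed. The samples analysed here hold no group with Rg1 and no LPS. The sources used here do not say whether the 5 libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples.

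Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups as its argument, which left 15362, and libraries were scaled by TMM factors. All 15 libraries entered a single quasi-likelihood fit with robust dispersions and the group as the only term, so that the 3 groups share their estimate of spread. Each pair of groups was compared by a two-sided quasi-likelihood F-test. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and genes with adjusted p under 0.05 are called changed. Normalised read counts are CPM, the counts as parts per M of the TMM-scaled library size, given as mean ± SD over 5 libraries, and log2 fold changes are given ± SE. The log2 CPM used for list scores and slopes had a prior count of 2. Where a group held 1 to 3 counts of a gene over its 5 libraries, the ratio of the counts per library size is given with its 95% exact counting interval. No fold is given where both groups are at or under 3 counts in all. In a library of 39489848 counts, 3 counts correspond to 0.076 parts per M of the unscaled total. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

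Before the data were examined, 30 gene lists were fixed for pathways, astrocyte states and other cell types, as were 13 study genes taken from the series title with the products of the inflammasome and NF-kB target cytokines. Of 527 list symbols, 522 were found in the files, 14 of them under another symbol of the GRCm38.p6 gene table, and the other 5 were not analysed here. Lists were tested with camera of limma at its preset inter-gene correlation of 0.01, with adjustment over the 30 lists. The test was repeated with a correlation estimated from the residuals. Per list, members are counted that passed over all genes tested, and for the study genes also adjusted over the list alone.

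The rule for naming genes was also fixed beforehand. For LPS against control and for Rg1 plus LPS against LPS it took the 8 genes with the highest and the 8 with the lowest log2 fold change among changed genes with a mean of at least 5 CPM and no overlap between the groups. Symbols made of Gm and digits, ending in Rik or missing were left out. For Rg1 plus LPS against control it took 4 and 4. The study genes are always named. Of each list, up to 4 members that rose and 4 that fell were taken in order of adjusted p, or up to 2 members with the smallest p where none passed. Of genes changed in opposite directions by LPS and by Rg1 plus LPS against LPS, it took the 10 with the smallest larger of both adjusted p, at 5 CPM or more and absolute log2 fold changes of 0.58 or more. Likewise it took up to 5 of those changed in the same direction.

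Both comparisons with the LPS group use the same 5 LPS libraries, which alone gives opposite changes. The slope of the Rg1 effect on the LPS effect across genes was therefore computed with the LPS libraries parted into 2 and 3, in all 10 ways and both ways round. The numbers of genes moved back or further were also counted with parted libraries. The methods were tested on simulated data with known differences. Of 100 genes made 2-fold different, the fit recovered 71 in LPS against control, 88 in Rg1 plus LPS against LPS and 77 in Rg1 plus LPS against control. Of 100 genes made 1.5-fold different it recovered 47, 57 and 60. No other genes were made different, far fewer than were called in the data, which makes the adjustment stricter than in the data.

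Alternatives tried were DESeq2 1.42.0 size factors and its Wald test, scaling to library size only, no filter on low counts, and a filter of 5 CPM in 5 libraries. Further ones were limma voom, limma on log2 FPKM with a pseudocount of 1 or 0.1, with a mean FPKM of at least 1 or without a filter, and only the compared groups in the fit. A term for the replicate number, 1 surrogate variable from sva 3.50.0, a threshold of 0.01 and leaving out each library in turn completed the planned set. Chosen after seeing the data were the removal of each library's trend with gene length (lowess span 0.3), the fit without control replicate 4 and LPS replicate 3, and the fit without Rg1 plus LPS replicates 1 and 4. Scripts in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.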

Results

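Polyadenylated RNA was sequenced from primary astrocytes of mouse brain, the glial cells that support neurons and respond to injury. The 15 libraries comprised 5 of untreated control cultures, 5 of cultures given lipopolysaccharide (LPS), the bacterial cell wall component that signals through TLR4, and 5 of cultures given ginsenoside Rg1, a saponin of ginseng, before LPS. Total counts per library averaged 36.8 M in the control group, 37.7 M in the LPS group and 38.7 M in the Rg1 plus LPS group. Mitochondrially encoded genes took 2.66 ± 0.119% of counts in control, 2.05 ± 0.3% in LPS and 4.06 ± 0.819% in Rg1 plus LPS (SD, n = 5 each). The first 3 principal components held 40.8%, 18.6% and 12% of the variance. On the first, the LPS libraries lay between 46.9 and 53.6 and all other libraries below 0. Among these others, control lay between -15.0 and -9.5 and Rg1 plus LPS between -43.7 and -36.6. On the second, the control libraries lay between -40.7 and -31.3 and all treated libraries between -5.65 and 35.6.

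The series title names the NLRP2 inflammasome and the TLR4, MyD88 and NF-kB pathway, and 13 study genes were chosen from it together with inflammasome products and NF-kB target cytokines. On GRCm38.p6, Nlrp2 lies on chromosome 7 at 5298547 to 5351035, Nlrp3 on 11 at 59541569 to 59566955, Pycard on 7 at 127991373 to 127993867 and Casp1 on 9 at 5298517 to 5307281. Il1b lies on chromosome 2 at 129364569 to 129371164, Il18 on 9 at 50554700 to 50581841, Il6 on 5 at 30013114 to 30019975 and Tnf on 17 at 35199367 to 35202007. Tlr4 lies on chromosome 4 at 66827551 to 66846581, Myd88 on 9 at 119335934 to 119340018, Nfkb1 on 3 at 135584655 to 135691969, Rela on 19 at 5637442 to 5648134 and Nfkbia on 12 at 55489409 to 55492647.

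The comparison of LPS with control shows what LPS, the study's in vitro stand-in for injury, changed in these astrocyte cultures. Chemokine, cytokine and NF-kB genes rose together. Cxcl1, a neutrophil attractant, went from 10.5 ± 2.01 CPM to 2242 ± 307 CPM (SD, n = 5; log2 fold change 7.74 ± 0.24, SE, adjusted p = 1.2e-12). Nfkbia, the NF-kB inhibitor that NF-kB itself induces, went from 23.7 ± 1.58 to 691 ± 62.8 CPM (log2 fold change 4.86 ± 0.15). Genes for the transcription factors Fosb and Nfatc2, the neurofilament gene Nefm and the astrocyte factor Sox9 fell.

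Among the study genes, 12 of 13 had enough counts to be tested. In LPS against control 8 of the 12 rose and 1 fell, and 10 changed when adjusted over the list alone. Nlrp3, the sensor of the best known inflammasome, rose from 0.128 ± 0.0839 to 9.05 ± 4.54 CPM (log2 fold change 6.13 ± 0.51, adjusted p = 1.84e-07). Il1b, an inflammasome product, had 3 counts over the control libraries and 1669 over the LPS libraries, a ratio of 559 with a 95% counting interval of 191 to 2710. Both genes were highest in LPS replicates 2 and 3 (Nlrp3 11.6 and 15.8 CPM against 4.92 to 6.80 CPM in the others), the LPS libraries in which the mean log2 CPM of microglia and macrophage markers was also highest (2.39 and 2.72 against 1.26 to 1.65). Tnf rose to 49.9 ± 13.7 CPM (log2 fold change 9.39 ± 0.44) and Il6 to 25.6 ± 4.19 CPM (6.37 ± 0.27). Nfkb1 rose by 2.54 ± 0.08 on the log2 scale, Rela by 0.80 ± 0.10 and the adaptor gene Myd88 by 0.95 ± 0.11. Tlr4, the LPS receptor, fell from 31.0 ± 1.95 to 21.1 ± 5.19 CPM (log2 fold change -0.56 ± 0.14, adjusted p = 0.008). For each of the 9 genes that changed, Nfkbia among them, every LPS library lay outside the range of the control libraries. Pycard, Casp1 and Il18 did not pass. Pycard had a log2 fold change of 0.16 ± 0.33, Casp1 0.28 ± 0.16 and Il18 -0.28 ± 0.11 (adjusted p = 0.0756, and 0.0213 without LPS replicate 3). Nlrp2 had 4 counts in all over the control libraries, 6 over the LPS libraries and 4 over the Rg1 plus LPS libraries, too few for a test. At this depth a modest difference in Nlrp2 was not detectable.

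**Figure D1:**
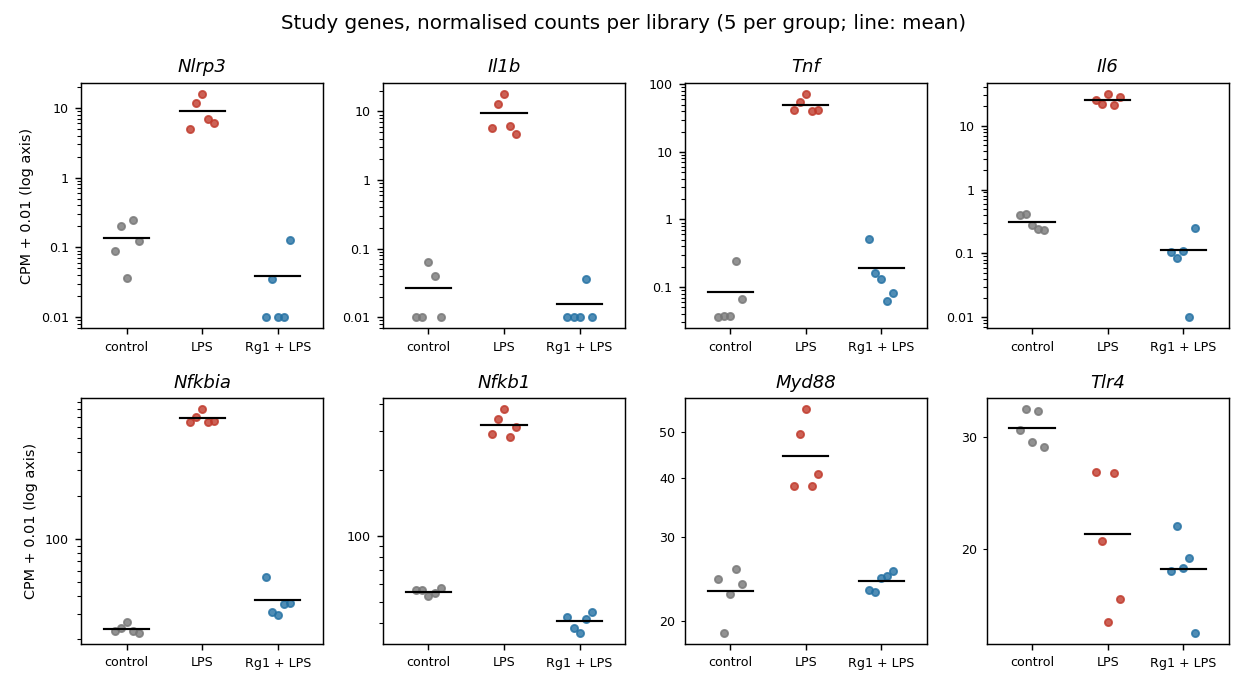
Normalised read counts (CPM plus 0.01, log axis) of 8 study genes in each library, by group; points are libraries (5 per group) and lines are means. For Nlrp3, Il1b, Tnf, Il6, Nfkbia, Nfkb1 and Myd88 every LPS library lies above every control and every Rg1 plus LPS library, and for Tlr4 every LPS library lies below every control library.

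All 17 chemokine genes tested rose (list adjusted p = 3.8e-78). Ccl20 rose from 0.0275 ± 0.0192 to 44.1 ± 7.74 CPM, Cxcl2 from 0.673 ± 0.174 to 395 ± 36.8 CPM, and Ccl2, which attracts monocytes, by 5.45 ± 0.19 on the log2 scale. Of 18 cytokine genes 15 rose (adjusted p = 4.37e-50), among them Csf3 (log2 fold change 4.06 ± 0.12), Csf1 (3.05 ± 0.14) and Csf2, whose 3 control counts against 3798 give a ratio of 1270 (95% counting interval 435 to 6170). The median log2 fold change of the list was 5.22, and 5.15 with genes of 3 or fewer counts set to that floor. All 11 NF-kB subunit and inhibitor genes rose (adjusted p = 3.8e-78), Nfkbie by 3.92 ± 0.14 and Nfkbiz by 3.55 ± 0.11. Of 14 genes for feedback inhibitors of inflammatory signalling 10 rose (adjusted p = 3.45e-31), among them Tnfaip3, which encodes the ubiquitin-editing enzyme A20 (log2 fold change 5.47 ± 0.17), Zc3h12a (4.52 ± 0.12) and Tnip1 (1.91 ± 0.09), while Otud1 fell (-1.41 ± 0.08). Of 12 genes for nitric oxide, prostaglandin and itaconate enzymes 8 rose and 2 fell (adjusted p = 1.06e-10). Nos2, the inducible nitric oxide synthase gene, had 2 counts in control and 9416 in LPS, a ratio of 4730 (95% counting interval 1310 to 39100). Acod1, which encodes the itaconate-forming enzyme, rose by 8.18 ± 0.41, and Ptges, for prostaglandin E synthase, by 1.48 ± 0.11. These 5 calls held with an estimated correlation.

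Interferon-stimulated genes rose in 15 of 35 cases (adjusted p = 5.78e-09; adjusted p = 0.554 with an estimated correlation). Gbp5 rose from 1.25 ± 0.260 to 142 ± 53.0 CPM, Rsad2 by 3.98 ± 0.33 on the log2 scale and Irf1 by 2.75 ± 0.20. Of 17 antigen presentation genes 9 rose (adjusted p = 0.00231; adjusted p = 0.554 with an estimated correlation), such as H2-K1 (log2 fold change 0.88 ± 0.13) and the peptide transporter gene Tap2 (0.85 ± 0.10). In the inflammasome list 4 of 11 rose, Nlrp3, Il1b, Casp4 (2.78 ± 0.35) and the pore-forming gasdermin gene Gsdmd (0.92 ± 0.14), with a list adjusted p = 0.0111, and adjusted p = 0.0998 with an estimated correlation. Of 18 TLR4 signalling genes 7 rose and 2 fell (adjusted p = 0.0184; adjusted p = 0.221 with an estimated correlation). Irak2 rose by 1.18 ± 0.10 and the co-receptor gene Cd14 by 1.70 ± 0.19. Without changed members that another list also holds, the inflammasome list had adjusted p = 0.0992 and the TLR4 list 0.0757. Here and below, such a removal picks members by their outcome and keeps shared members that did not change. It can therefore end or begin a call by itself.

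Among lists that fell, glucocorticoid receptor targets held with an estimated correlation (adjusted p = 0.00363; adjusted p = 0.0218 with an estimated correlation), with 7 of 16 down and 2 up. Sgk1 had a log2 fold change of -1.46 ± 0.23, Klf9 -1.08 ± 0.12 and Tsc22d3 -0.83 ± 0.11, while Cdkn1a rose by 0.83 ± 0.10. Of 28 astrocyte identity genes 12 fell and 1 rose (adjusted p = 1.94e-05; adjusted p = 0.663 with an estimated correlation). Sox9, a transcription factor of the astrocyte lineage, went from 193 to 70.1 CPM (log2 fold change -1.46 ± 0.12), the folate enzyme gene Aldh1l1 had -0.52 ± 0.11 and S100b -0.57 ± 0.12, while Id3 rose by 1.13 ± 0.13. By the rule for single genes, the lowest fold changes were those of Fosb (91.7 ± 14.4 to 2.21 ± 0.674 CPM, log2 fold change -5.37), Nfatc2 (50.7 ± 2.98 to 2.6 ± 0.671 CPM, -4.29), Ahrr (-3.95), Nptx1 (-3.74), Cyp1a1 (-3.66), Nefl (-3.41), Nefm (-2.80) and Rgs2 (-2.77). Ahrr and Cyp1a1 are target genes of the aryl hydrocarbon receptor, and Nefl and Nefm encode neurofilament proteins of neurons. None of 17 microglia and macrophage markers passed in edgeR, while 2 rose at an unadjusted p under 0.05 and 1 rose in DESeq2 and in limma voom. Their median log2 fold change was 0.29 (list adjusted p = 0.701, and 0.0412 without control replicate 4).

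In all, 3635 of 15362 genes changed (23.66%), 2127 higher and 1508 lower, of which 764 changed at least 2-fold, 471 higher and 293 lower. With scaling to library size only, 45.9% of the changed genes were higher, against 58.5% with TMM. Groups did not overlap for 3132 genes (20.39%), where chance gives 0.794%.

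The comparison of Rg1 plus LPS with LPS asks what Rg1 given beforehand changed in cells under LPS. All 97 genes that LPS had raised at least 8-fold fell. Cxcl1 fell from 2242 ± 307 to 6.35 ± 2.17 CPM (SD, n = 5; log2 fold change -8.46 ± 0.25, SE, adjusted p = 3.37e-13) and Cxcl2 from 395 ± 36.8 to 0.821 ± 1.02 CPM (-8.91). Sele, which encodes the adhesion protein E-selectin, fell from 117 ± 18.4 to 0.0689 ± 0.0708 CPM (-10.65). Of the genes listed, 9 of 13 mitochondrially encoded ones rose, and 17 of 24 of cholesterol synthesis and uptake and 17 of 23 of extracellular matrix fell, but these list calls were lost with an estimated correlation (adjusted p = 0.375 to 0.399).

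Of the 12 study genes tested 8 fell, and 9 changed when adjusted over the list alone. The ninth was Il18, with a log2 fold change of 0.26 ± 0.11 (adjusted p = 0.0679 over all genes, 0.0192 to 0.0419 without LPS replicate 3 or Rg1 plus LPS replicate 4, and 0.0439 over the list alone). Nlrp3 fell to 0.0288 ± 0.0517 CPM (log2 fold change -8.10 ± 0.61, adjusted p = 3.13e-08), Tnf to 0.181 ± 0.186 CPM (-8.06 ± 0.39) and Il6 to 0.102 ± 0.0863 CPM (-7.90 ± 0.30). Il1b had 1 count in the Rg1 plus LPS libraries, a ratio of 1850 between the groups (95% counting interval 332 to 73100). Nfkbia had a log2 fold change of -4.21 ± 0.15, Nfkb1 -2.99 ± 0.08, Rela -0.95 ± 0.10 and Myd88 -0.88 ± 0.11. For these 8 genes the groups did not overlap. Pycard (0.29 ± 0.33), Casp1 (0.19 ± 0.16) and Tlr4 (-0.18 ± 0.14) did not pass, and with the gene length trend removed Casp1 was at -0.016 and Tlr4 at 0.03.

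Of 17 chemokine genes 16 fell (list adjusted p = 4.27e-53), with Ccl2 at a log2 fold change of -7.47 ± 0.21, Ccl7 at -7.09 ± 0.22 and Ccl4 at -9.35. Ccl20 had 2 counts in Rg1 plus LPS against 8085 in LPS, a ratio of 4480 (95% counting interval 1240 to 37000). Of 18 cytokine genes 15 fell (adjusted p = 5.51e-37; median log2 fold change -6.21, and -5.94 with genes of 3 or fewer counts set to that floor), among them Lif (-5.50 ± 0.22) and Csf3 (-4.99 ± 0.13). Csf2 gave a ratio of 1400 (95% counting interval 480 to 6810). All 11 NF-kB genes fell (adjusted p = 1.87e-58), Nfkbiz at -4.79 ± 0.12 and Nfkbie at -4.37 ± 0.15. Of 14 feedback inhibitor genes 10 fell and 1 rose (adjusted p = 8.29e-20): Tnfaip3 had -6.74 ± 0.18 and Zc3h12a -4.98 ± 0.12, while Otud1 rose by 0.73 ± 0.08. Of the nitric oxide, prostaglandin and itaconate genes 9 of 12 fell (adjusted p = 5.91e-12). Nos2 had 1 count against 9416, a ratio of 10400 (95% counting interval 1870 to 412000), Acod1 had -9.97 ± 0.47 and Gch1, for the enzyme that starts synthesis of the nitric oxide synthase cofactor, -2.76 ± 0.12. Of 11 genes of the A2 astrocyte list 7 fell (adjusted p = 0.0032), among them Ptx3 (-3.48 ± 0.30), Cd14 (-2.86 ± 0.20) and Ptgs2 (-2.73 ± 0.60), and this call ended without changed members that another list also holds (adjusted p = 0.0603). These 6 calls held with an estimated correlation, the A2 list at adjusted p = 0.0291. Markers of microglia and macrophages were not called as a list (list adjusted p = 0.0699, and 0.698 with an estimated correlation). Of these markers 10 of 17 fell, with Itgam at -2.73 ± 0.43 and Ctss at -2.08 ± 0.39, while Tmem119 and Cd68 did not pass.

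Interferon-stimulated genes fell in 19 of 35 cases (adjusted p = 5.49e-08; adjusted p = 0.425 with an estimated correlation), Gbp5 at -8.31 ± 0.36 and Irf1 at -4.17 ± 0.22 on the log2 scale. Antigen presentation genes fell in 10 of 17 (adjusted p = 0.0117; adjusted p = 0.528 with an estimated correlation), H2-K1 at -0.78 ± 0.13 and Tap2 at -0.79 ± 0.10. Of 24 genes of cholesterol synthesis and uptake, 17 fell (adjusted p = 8.01e-06; adjusted p = 0.399 with an estimated correlation). Stard4 had a log2 fold change of -1.19 ± 0.10. Of 23 extracellular matrix genes 17 fell and 1 rose (adjusted p = 0.000209; adjusted p = 0.375 with an estimated correlation): fibronectin Fn1 had -0.71 ± 0.10, the basement membrane collagens Col4a1 -0.94 ± 0.10 and Col4a2 -1.07 ± 0.11, and the collagenase Mmp13 -3.27 ± 0.29. Long genes tended to be lower in this comparison. With that trend removed, the cholesterol (adjusted p = 3.71e-07) and extracellular matrix lists (0.000936) were still called as lower at the preset correlation. Across genes, which are not independent replicates, Spearman's rho between log2 fold change and gene length was -0.33, with a median of 0.24 in the shortest 25% of genes and -0.19 in the longest 25%.

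Among the genes that rose, 9 of 13 mitochondrially encoded genes passed (adjusted p = 1.39e-05; adjusted p = 0.375 with an estimated correlation), such as CYTB (log2 fold change 1.11 ± 0.11), ND4 (1.22 ± 0.13) and COX3, which went from 46.7 ± 6.82 to 128 ± 48.0 CPM (1.45). In Rg1 plus LPS replicate 5 the mean log2 CPM of the list (7.11) lay within the range of the LPS libraries (6.39 to 7.45). As a share of all counts, its 2.77% lay above the LPS libraries (1.575% to 2.372%). The lowest of these was LPS replicate 5, and shared cultures of equal replicate number are not excluded for these groups. By the rule for single genes, the highest fold changes were those of Adrb1, the beta-1 adrenergic receptor gene (3.02 ± 0.338 to 17.9 ± 3.84 CPM, log2 fold change 2.57), Klf15 (2.20 ± 0.845 to 12.0 ± 2.58 CPM, 2.46), Rgs2 (2.15), Ppp1r3c (1.79), the Notch target genes Hes1 (15.2 ± 2.43 to 48.4 ± 7.42 CPM, 1.67) and Hey1 (1.46), and Zfp395 (1.58). Of these, Adrb1, Klf15 and Hes1 had control levels of 10.8 ± 0.487, 4.71 ± 1.27 and 40.9 ± 4.79 CPM. Of 28 astrocyte identity genes 9 rose and 2 fell (adjusted p = 0.0644; adjusted p = 0.77 with an estimated correlation, and 0.0284 with a term for the replicate number), with Sox9 at 0.81 ± 0.12 and S100b at 0.78 ± 0.12.

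**Figure D2:**
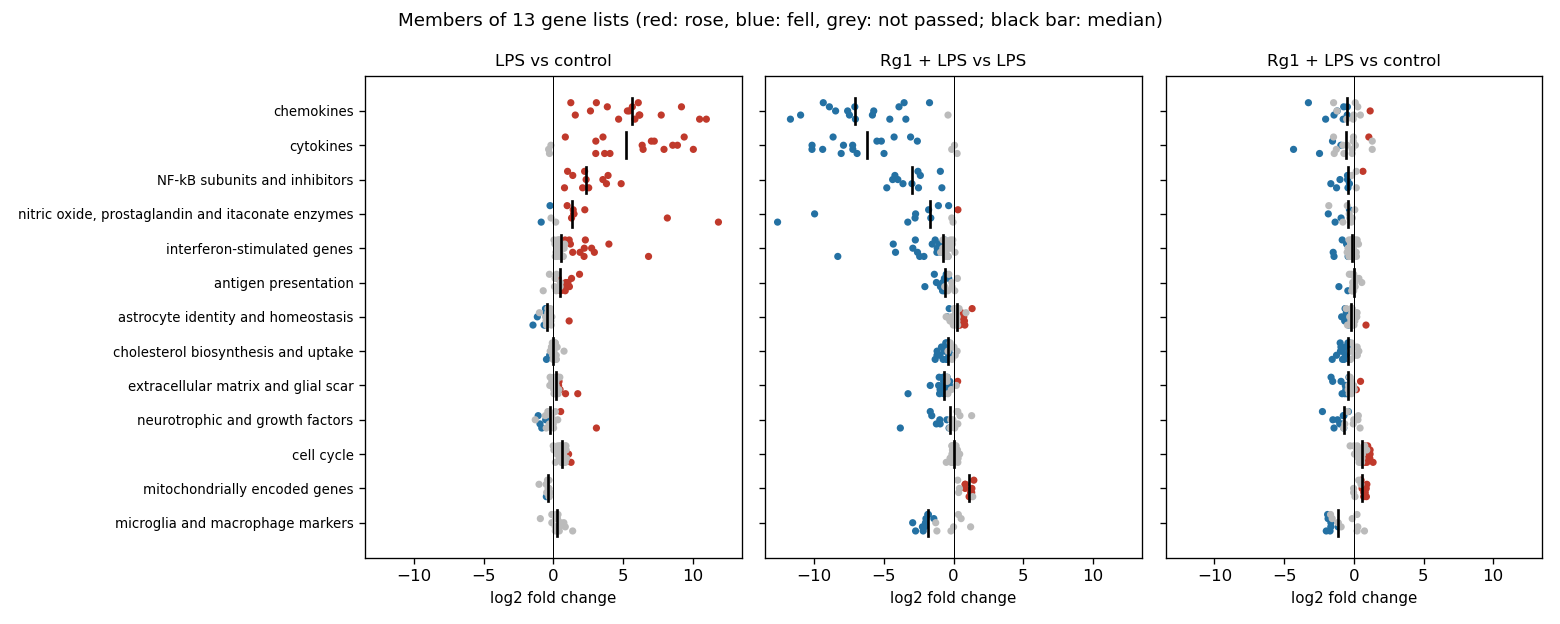
Log2 fold changes of the members of 13 gene lists in the 3 comparisons; each point is a gene (red rose, blue fell, grey did not pass) and black bars are list medians, and values of genes with few counts in a group depend on the prior count. The chemokine median is 5.67 in LPS against control, -7.04 in Rg1 plus LPS against LPS and -0.51 in Rg1 plus LPS against control.

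In all, 6976 genes changed (45.41%), 3412 higher and 3564 lower, of which 1253 changed at least 2-fold, 448 higher and 805 lower. With scaling to library size only, which shifted the median of all genes to 0.14, 65% of the changed genes were higher, against 48.9% with TMM at a median of 0.028. Groups did not overlap for 4227 genes (27.52%).

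The comparison of Rg1 plus LPS with control asks how far cells given Rg1 and LPS stood from untreated cells. Inflammatory genes that LPS had raised mostly did not pass or were below control. Of the genes listed, 16 of 24 of cholesterol synthesis and uptake and 10 of 18 for growth factors were lower, and 8 of 13 mitochondrially encoded and 12 of 30 cell cycle genes higher. All 4 list calls were lost with an estimated correlation (adjusted p = 0.256 to 0.802), and the mitochondrial one also with the length trend removed (0.0666). Ccl2 was at 11.4 CPM against 46.2 CPM in control (n = 5 each; log2 fold change -2.02 ± 0.17, SE, adjusted p = 2.96e-07) and Lif at 13.8 against 76.1 CPM (-2.46 ± 0.19).

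Of the study genes 2 rose and 3 fell, and 5 changed when adjusted over the list alone. Nfkbia was higher (37.4 ± 10 against 23.7 ± 1.58 CPM, log2 fold change 0.66 ± 0.13, adjusted p = 0.00113). Tlr4 (-0.74 ± 0.14, adjusted p = 0.000672), Nfkb1 (-0.45 ± 0.08) and Il6 (-1.53 ± 0.42, adjusted p = 0.0098, and 0.0601 in limma on log2 FPKM with a pseudocount of 1) were lower. Casp1 had a log2 fold change of 0.47 ± 0.16 (adjusted p = 0.0314). That call ended without any of 6 libraries, namely replicates 1, 3 and 4 of Rg1 plus LPS and replicates 1, 2 and 4 of control (adjusted p up to 0.0843), and with the gene length trend removed (0.19). Nlrp3 had -1.97 ± 0.92 (adjusted p = 0.105, and 0.0218 without Rg1 plus LPS replicate 5, which holds 5 of the group's 6 counts), Tnf 1.32 ± 0.78 (0.197), Rela -0.15 ± 0.10 (0.0279 without Rg1 plus LPS replicate 1), Myd88 0.07 ± 0.11, Pycard 0.46 ± 0.33 and Il18 -0.02 ± 0.11, and the last also took positive values under other settings. For Il1b, with 1 and 3 counts, and for Nlrp2 no fold is given.

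Of 11 A2 astrocyte genes 7 fell (adjusted p = 0.000611; adjusted p = 0.048 with an estimated correlation), among them Emp1 (log2 fold change -1.14 ± 0.17), Cd109 (-0.85 ± 0.10) and Cd14 (-1.16 ± 0.20). The other 9 lists called lost the call with an estimated correlation. Of 24 cholesterol genes 16 fell (adjusted p = 1.02e-09; adjusted p = 0.327 with an estimated correlation), Stard4 at -1.24 ± 0.10 and Hsd17b7 at -0.92 ± 0.09. Of 18 neurotrophic and growth factor genes 10 fell (adjusted p = 0.000611; adjusted p = 0.256 with an estimated correlation), such as Hbegf (-1.17 ± 0.16), Bdnf (-0.71 ± 0.11), Fgf2 (-0.88 ± 0.10) and Pdgfa (-0.72 ± 0.08). Extracellular matrix genes fell in 12 of 23 and rose in 2 (adjusted p = 0.00227; adjusted p = 0.48 with an estimated correlation), Fn1 at -0.66 ± 0.10 and Mmp13 at -1.52 ± 0.28. Of 11 NF-kB genes 7 fell and 1, Nfkbia, rose (adjusted p = 0.00643; adjusted p = 0.327 with an estimated correlation), with Bcl3 at -1.65 ± 0.22 and Nfkbiz at -1.24 ± 0.11. Chemokine genes fell in 8 of 17 (adjusted p = 0.0139; adjusted p = 0.327 with an estimated correlation). Of 12 nitric oxide, prostaglandin and itaconate genes 4 fell (adjusted p = 0.0109; adjusted p = 0.327 with an estimated correlation), among them Gch1 (-1.34 ± 0.12) and Ptgs1 (-0.91 ± 0.10). Gene length went with this comparison as well (Spearman's rho across genes -0.31).

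Cell cycle genes rose in 12 of 30 cases (adjusted p = 0.00427; adjusted p = 0.802 with an estimated correlation), such as Aurka (3.95 to 10.3 CPM, log2 fold change 1.38 ± 0.33), Birc5 (1.17 ± 0.33) and Cdc20 (1.04 ± 0.28). The mean log2 CPM of the list was clearly above control (3.01 to 3.79) only in Rg1 plus LPS replicates 2 and 5 (4.55 and 4.46), with 3.68 to 3.83 in the other 3. Mitochondrially encoded genes rose in 8 of 13 (adjusted p = 0.00427; adjusted p = 0.668 with an estimated correlation, and 0.0666 with the length trend removed), CYTB by 0.71 ± 0.11 and COX2 by 0.89 ± 0.17. Rg1 plus LPS replicate 5 did not share this rise. Its mean log2 CPM of the list was 7.11, below the control libraries (7.42 to 7.63), with 8.01 to 8.50 in the other 4. As a share of all counts, the 2.77% of that library lay within the control range (2.486% to 2.795%). Immediate early and heat shock genes went both ways, 4 up and 8 down of 16 (adjusted p = 0.0277; adjusted p = 0.668 with an estimated correlation): Fos rose from 24.2 ± 3.73 to 76.8 ± 27.1 CPM (1.67 ± 0.21) and the chaperone gene Hspa8 by 0.63 ± 0.10, while Fosb (-4.00 ± 0.39), Egr3 (-2.66 ± 0.23), Nr4a1 (-2.16 ± 0.21) and Junb (-1.06 ± 0.11) fell. That call ended without Rg1 plus LPS replicate 3 or 5 (adjusted p = 0.0678 to 0.0847). By the rule for single genes, Snai2 (4.20 ± 1.17 to 18.8 ± 6.71 CPM, log2 fold change 2.16), Fos, Atoh8 (1.54) and Lime1 (1.46) were highest, and Nfatc2 (1.48 ± 0.406 CPM, -5.10), Sele (-4.79), Nptx1 (-4.71) and Ahrr (-4.35) lowest. In all, 5671 genes changed (36.92%), 2884 higher and 2787 lower, of which 778 changed at least 2-fold. With scaling to library size only, 63.9% of the changed genes were higher, against 50.9% with TMM. Groups did not overlap for 4025 genes (26.2%).

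**Figure D3:**
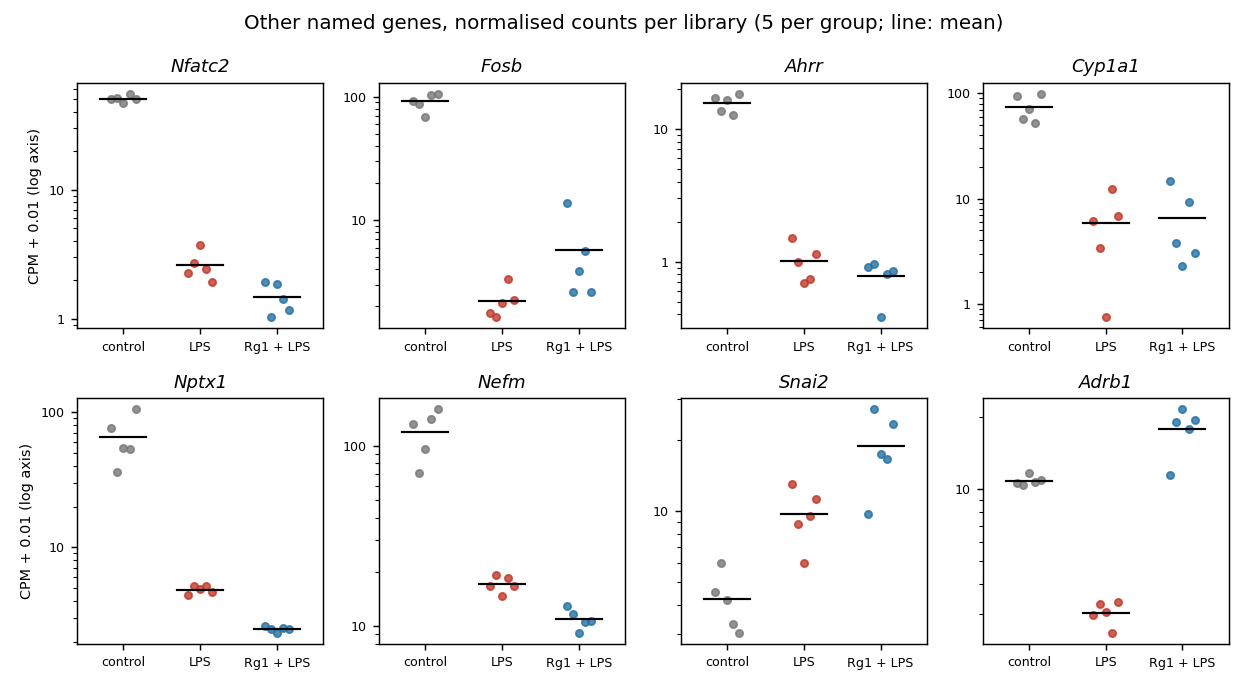
Normalised read counts (CPM plus 0.01, log axis) of 8 other named genes in each library, by group; points are libraries (5 per group) and lines are means. Nfatc2, Fosb, Ahrr, Cyp1a1, Nptx1 and Nefm are lower in both treated groups than in control, Snai2 is highest in Rg1 plus LPS, and Adrb1 is lowest in LPS.

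Set side by side, the comparisons show where genes changed by LPS stood in cells given Rg1 first. Back and further are directions between groups here. Nothing shows that these genes first changed in the Rg1 plus LPS cultures, and a lack of LPS action there cannot be told apart. Of the genes changed by LPS, 2265 changed in the opposite direction in Rg1 plus LPS against LPS. Of these, 1505 were up with LPS and down in that comparison (493.5 expected if the calls were independent), and 760 the reverse (334.9 expected). In the same direction 198 changed further, 57 up and 141 down (472.4 and 349.9 expected), a number that was 394 with 1 surrogate variable and 85 at a threshold of 0.01. Since the LPS libraries are shared, the counts were repeated with them parted: over 20 fits, 1073 to 1611 genes changed in opposite directions (at most 729.6 expected) and 71 to 401 in the same direction (at most 716.8 expected). The 10 genes named for moving back were Ccl20, Tlr2 (8.00, 348 and 4.54 CPM in control, LPS and Rg1 plus LPS), Zc3h12a, Csf3, Ier3 (90.7, 603 and 97.0 CPM), Nfkb1, Nfkbiz, Nos2, Ripk2 (16.4, 410 and 14.3 CPM) and Tnfaip3. Those named for moving further were Arhgap29 (151, 87.9 and 51.1 CPM), Slc26a2 (39.0, 12.2 and 5.31 CPM), Tet3, Creb5 and Klf10, all down in both comparisons.

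Of the 471 genes that LPS raised at least 2-fold, 295 did not differ from control in Rg1 plus LPS, 57 were above and 119 below control, and 428 were lower than in LPS. Their median log2 fold change was 1.70 in LPS against control and -0.19 in Rg1 plus LPS against control. Of the 293 genes that LPS lowered at least 2-fold, 122 did not differ from control in Rg1 plus LPS, 166 were below and 5 above. Against LPS, 142 of them were higher and 19 lower. The median log2 fold change of these genes was -1.37 in LPS against control and -0.74 in Rg1 plus LPS against control. Across all tested genes the slope of the Rg1 effect on the LPS effect was -0.74 with the LPS libraries parted (covariance -0.315). Genes fully at the control level in Rg1 plus LPS would give -1 only without sampling error in the LPS effects. Such error makes the parted slope smaller in size, so -0.74 is not the share of the LPS effect that was absent. Values over the 20 ways of parting had an SD of 0.08 and a range of -0.86 to -0.58. Unparted, the slope was -0.86 (covariance -0.341) against -0.50 (covariance -0.022) in simulated data without group differences, and parted simulated data gave -0.003. Over only the genes changed by LPS, the parted slope was -0.87. No p-value is given, since genes are not independent replicates.

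Genes that stood apart from control in the same direction in both treated groups, among them the 57 and 166 genes just given, numbered 1070, 504 higher (399.3 expected if independent) and 566 lower (273.6 expected), while 482 were higher in LPS and lower in Rg1 plus LPS (385.9 expected) and 112 the reverse (283.1 expected). Genes higher in LPS thus showed a like excess in both directions, and only those lower in LPS an excess in the same direction alone. With the control libraries parted, 434 to 551 genes moved the same way (at most 308.2 expected) and 263 to 427 in opposite ways (at most 322.8 expected), the latter also above the number expected in each of the 20 fits. Among genes named above, Nfatc2 had 50.7, 2.6 and 1.48 CPM in control, LPS and Rg1 plus LPS, Cyp1a1 74.5, 5.88 and 6.59 CPM, and Nefm 120, 17.2 and 11.0 CPM. Tiparp, a further aryl hydrocarbon receptor target chosen after its values were seen, had 294, 55.4 and 53.1 CPM.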

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

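Levels of the study genes, mean log2 CPM of each gene list and measures of library quality were searched for a library far from the other 4 of its group. Of 135 groups searched, 8 held such a library, where chance gives about 1 in 20, or 6.8, so the number itself is near chance. None of these values was given an explanation.

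Among study genes in Rg1 plus LPS, Nfkbia stood at 54.66 CPM in replicate 1 against 29.71 to 35.76 CPM in the others. Tnf stood at 0.5073 CPM in the same library against 0.05322 to 0.1489 CPM. Nlrp3 stood at 0.1192 CPM in replicate 5 against 0 to 0.02482 CPM, and Il1b at 0.02661 CPM in replicate 4 against 0 in the others, which is a single count. In control replicate 4, Tnf stood at 0.2341 CPM against 0.02583 to 0.05606 CPM. The microglia and macrophage list had a mean log2 CPM of 2.767 in that library against 1.122 to 1.392, and the oligodendrocyte lineage list 5.607 against 5.1 to 5.207. In LPS replicate 3 the glycolysis and hypoxia list stood at 6.623 against 6.515 to 6.531.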

How the results depend on the processing

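The removal of the gene length trend and the fits without pairs of libraries were chosen after seeing the data. Of 519 values of counts, lists and slopes under alternatives, 488 stayed within 1.5 times (slopes: within 1 SD) of the reported value and 31 moved. Of the results for named genes, 10307 kept direction and side of the threshold, 585 lost and 23 gained the call, and 20 changed sign. In the cases below the cause was not tested, except where fewer genes or a stricter threshold give it.

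At a threshold of 0.01, 2051 genes changed in LPS against control (1328 higher, 723 lower) and 3593 in Rg1 plus LPS against control (1759 higher, 1834 lower). In Rg1 plus LPS against LPS 2260 were higher, 1292 genes moved back and 85 further. Genes changed at least 2-fold numbered 403, 540 and 328 in LPS against control, Rg1 plus LPS against LPS and Rg1 plus LPS against control with the filter of 5 CPM, which tests 11016 genes. They numbered 280, 347 and 157 in limma on log2 FPKM plus 1, 399, 573 and 301 with 0.1, and 296, 376 and 157 with 1 and no filter. Lower in Rg1 plus LPS against LPS were 2281 genes with a pseudocount of 1 and 2290 with 0.1. With 1 surrogate variable 394 genes moved further. An estimated correlation called 6, 6 and 1 lists. The slope was -0.6192 without a filter, -0.845 with that of 5 CPM, -0.8583 unparted and -0.8719 over genes changed by LPS.

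With the length trend removed, Casp1 was at -0.016, Tlr4 at 0.03, Vim at -0.002, Manf at -0.084 and Tpi1 at -0.029 in Rg1 plus LPS against LPS, and Myd88 at -0.072 and Manf at -0.039 in Rg1 plus LPS against control. Il18 in Rg1 plus LPS against control was at 0.043 with library size only, 0.033 on log2 FPKM plus 1 with and without a filter, 0.04 with 0.1, 0.014 with 1 surrogate variable, 0.045 without control replicate 4 and LPS replicate 3, 0.069 without Rg1 plus LPS replicates 1 and 4, and -0.089 to 0.051 without single libraries. Myd88 there lay between -0.001 and 0.112 without single libraries, and Hspa1a, at 1.524 with all libraries, fell to -0.039 without Rg1 plus LPS replicates 1 and 4.

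Without single libraries, 2847 to 4440, 6290 to 7327 and 4903 to 5836 genes changed in the 3 comparisons, 1825 to 2722 moved back, and the slope was -0.76 to -0.6974. Residuals of libraries with equal replicate numbers correlated at -0.222 to 0.155 for control and LPS and -0.218 to 0.136 for control and Rg1 plus LPS, which gives no sign of pairs. For LPS and Rg1 plus LPS they correlated at 0.05 to 0.424, and 6 of 10 libraries went best with their own number, so that shared cultures of these groups are not excluded. With a term for the replicate number 4113, 7254 and 6027 genes changed. The spread within groups was unequal. Chi-square per degree of freedom between pairs of libraries was 7.12 to 26.62 in control, 17.45 to 77.94 in LPS and 23.06 to 142.38 in Rg1 plus LPS. With only the compared groups in the fit, 4521 of 14807, 5997 of 14922 and 5561 of 14960 genes changed. The shared estimate of spread therefore bears on how the numbers of the 3 comparisons stand to each other. With the length trend removed 3644, 6018 and 4738 changed, of which 3394, 4961 and 3841 are the same genes as without the removal. Depth limits Nlrp2, Il1b and other genes with a few counts per group. In simulated data 1.5-fold changes were recovered for 47% to 60% of genes. Far fewer genes differed there than in the data, so these shares do not give the recovery in the data.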

Other observations

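In LPS against control, 6 of 13 pan-reactive astrocyte genes rose and 2 fell (list adjusted p = 0.0163; adjusted p = 0.433 with an estimated correlation), with Steap4 at a log2 fold change of 2.71 ± 0.34, Timp1 at 1.09 ± 0.13 and the hyaluronan receptor gene Cd44 at 0.65 ± 0.09. That call ended without LPS replicate 3 (adjusted p = 0.0607) and without changed members that another list also holds (0.3). Ependymal markers fell in 4 of 8 (adjusted p = 0.0122; adjusted p = 0.554 with an estimated correlation), with Rsph1 at -0.47 ± 0.10. Neuron markers fell in 2 of 10 and rose in 1 (adjusted p = 0.0187; adjusted p = 0.171 with an estimated correlation), the 2 being Nefl and Nefm. Cell cycle genes rose in 3 of 30 (adjusted p = 0.0226; adjusted p = 0.869 with an estimated correlation), with Aurka at 1.27 ± 0.33, and the call ended without LPS replicate 1 or 5 or control replicate 4 (adjusted p = 0.056 to 0.152). Mitochondrially encoded genes fell in 2 of 13 (adjusted p = 0.0149; adjusted p = 0.71 with an estimated correlation), and the call ended without LPS replicate 5 (0.0553) and with the length trend removed (0.0517).

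Of 13 pan-reactive genes in Rg1 plus LPS against LPS, 8 fell and 3 rose (adjusted p = 0.00356; adjusted p = 0.306 with an estimated correlation, and 0.0626 without changed members that another list also holds). Cd44 stood at -1.43 ± 0.09, Steap4 at -3.31 ± 0.35 and Aspg at 0.90 ± 0.16. Immediate early and heat shock genes fell in 6 of 16 and rose in 2 (adjusted p = 0.0267; adjusted p = 0.528 with an estimated correlation, and 0.0679 without Rg1 plus LPS replicate 5), with Junb at -2.17 ± 0.11, Ier2 at -1.87 ± 0.12 and Egr1 at -1.33 ± 0.17. Neurotrophic and growth factor genes fell in 8 of 18 (adjusted p = 0.0644), with Bmp2 at -3.82 ± 0.27 and Bdnf, a neurotrophin gene, at -1.23 ± 0.11. In Rg1 plus LPS against control, microglia markers fell in 7 of 17 (adjusted p = 0.0786), and the angiogenic receptor gene Flt1 of the endothelial list stood at -1.76 ± 0.18, with 3 of 7 down (adjusted p = 0.0594).

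The lists not described elsewhere were not called. In LPS against control they were complement (2 of 12 rose, adjusted p = 0.951), A1 astrocyte genes (5 of 12 rose and 1 fell, 0.303), A2 genes (3 rose and 3 fell of 11, 0.763), cholesterol (2 of 24 fell, 0.748), NRF2 targets (1 rose and 1 fell of 21, 0.622), unfolded protein and stress response (1 rose and 2 fell of 20, 0.763) and glycolysis and hypoxia (2 rose and 5 fell of 19, 0.612). The others were extracellular matrix (6 of 23 rose, 0.173), neurotrophic factors (2 rose and 5 fell of 18, 0.303), immediate early genes (6 rose and 3 fell of 16, 0.612), endothelial (1 of 7 rose, 0.622) and fibroblast and mural markers (1 of 12 fell, 0.984), and oligodendrocyte markers, none of 7 in edgeR, with 2 up and 2 down at an unadjusted p under 0.05 and 1 up in DESeq2 and in limma voom (0.951).

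For Rg1 plus LPS against LPS they were TLR4 signalling (2 rose and 8 fell of 18, adjusted p = 0.0644, and 0.041 without Rg1 plus LPS replicate 1), inflammasome (2 rose and 4 fell of 11, 0.133), complement (4 of 12 fell, 0.133), A1 genes (1 rose and 5 fell of 12, 0.118), NRF2 targets (3 rose and 2 fell of 21, 0.492), glucocorticoid receptor targets (7 rose and 2 fell of 16, 0.0712) and unfolded protein response (6 rose and 4 fell of 20, 0.671). Glycolysis had 3 up and 6 down of 19 (0.492), neuron markers 2 up and 1 down of 10 (0.661), oligodendrocyte markers 2 up and 2 down of 7 (0.823), endothelial markers 2 of 7 down (0.0628), fibroblast and mural markers 2 of 12 down (0.259) and ependymal markers 5 of 8 up (0.0644). Of 30 cell cycle genes none passed in edgeR, at an unadjusted p under 0.05, in DESeq2 or in limma voom (0.588).

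For Rg1 plus LPS against control they were TLR4 signalling (1 rose and 3 fell of 18, adjusted p = 0.933), inflammasome (4 rose and 1 fell of 11, 0.715), cytokines (1 rose and 4 fell of 18, 0.0542), feedback inhibitors (3 rose and 4 fell of 14, 0.608), interferon-stimulated genes (6 of 35 fell, 0.16), antigen presentation (2 of 17 fell, 0.907) and complement (4 of 12 fell, 0.0553). Pan-reactive genes had 1 up and 3 down of 13 (0.128), A1 genes 1 of 12 down (0.451), astrocyte identity 1 up and 8 down of 28 (0.119), NRF2 targets 1 of 21 up (0.889), glucocorticoid receptor targets 3 up and 4 down of 16 (0.649) and unfolded protein response 5 up and 5 down of 20 (0.907). Glycolysis had 2 up and 8 down of 19 (0.119), neuron markers 2 up and 3 down of 10 (0.119), oligodendrocyte markers 2 up and 1 down of 7 (0.907) and fibroblast and mural markers 1 of 12 down (0.161). Of 8 ependymal markers none passed in edgeR, at an unadjusted p under 0.05, in DESeq2 or in limma voom (0.946).

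Median, mean or test direction of a list differed in sign for complement, cholesterol, NRF2 targets, immediate early genes and oligodendrocyte markers in LPS against control. The same held for inflammasome, glycolysis, immediate early genes and oligodendrocyte markers in Rg1 plus LPS against LPS. Against control, Rg1 plus LPS showed this for inflammasome, glucocorticoid receptor targets, unfolded protein response, neuron and oligodendrocyte markers.

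Calls of some lists also began under other settings, all with the preset correlation. With an estimated correlation and no other change, these lists had adjusted p = 0.215 to 0.77 in Rg1 plus LPS against LPS and 0.327 to 0.9 in Rg1 plus LPS against control. With a term for the replicate number, Rg1 plus LPS against LPS called astrocyte identity and ependymal markers (adjusted p = 0.0284 each, up), endothelial markers (0.032, down) and microglia markers (0.0495, down), and Rg1 plus LPS against control called cytokines, complement, astrocyte identity and endothelial markers (0.035 each, down). With scaling to library size only, neurotrophic factors (0.0367), microglia (0.0249) and endothelial markers (0.0357) were down against LPS, and cytokines (0.0144), complement (0.0264), microglia (0.0298) and endothelial markers (0.0374) against control. With the length trend removed, microglia markers were down against LPS (0.02), and cytokines (0.0198), complement (0.0327), pan-reactive genes (0.0491), glycolysis (0.0416) and microglia markers (0.0198) against control. Without changed members that another list also holds, glucocorticoid receptor targets were up against LPS (0.047).

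Leaving out 1 library also began calls that the full data did not give, again with the preset correlation only (adjusted p = 0.215 to 0.901 with an estimated one and all libraries). In Rg1 plus LPS against LPS this held for astrocyte identity without Rg1 plus LPS replicate 1 or 4 or LPS replicate 2 or 3 (adjusted p = 0.00235 to 0.0454), ependymal markers without Rg1 plus LPS replicate 1 or 4 or LPS replicate 3 (0.0107 to 0.0493), neurotrophic factors without Rg1 plus LPS replicate 2 or 3 or LPS replicate 2 (0.0392 to 0.0448) and microglia markers without Rg1 plus LPS replicate 3 or LPS replicate 1 or 5 (0.0279 to 0.0448). Endothelial markers passed there without any library except Rg1 plus LPS replicate 1 and LPS replicate 3 (0.0249 to 0.0494). Cytokines and endothelial markers passed in Rg1 plus LPS against control without Rg1 plus LPS replicate 2, 3 or 5 or control replicate 1, 2, 3 or 5 (0.0208 to 0.0455), complement without the same libraries except control replicate 2 (0.0208 to 0.0426), and microglia markers without Rg1 plus LPS replicate 3 or control replicate 1, 2, 3 or 5 (0.0334 to 0.0499). Interferon-stimulated genes passed without Rg1 plus LPS replicate 5 or control replicate 5 (0.0228 to 0.038), fibroblast and mural markers without Rg1 plus LPS replicate 5 (0.0291), neuron markers without control replicate 2 (0.00805) and astrocyte identity without Rg1 plus LPS replicate 3 (0.00784).

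Replicates 1 and 4 of Rg1 plus LPS stood apart from the other 3 libraries of their group, as was noticed after the values were seen. Between the gene counts of 2 libraries, chi-square per degree of freedom (near 1 for counting error alone) was 23.06 for this pair, 55.79 to 142.38 between either and the others, and 23.11 to 50.82 among the others. The interferon-stimulated list had a mean log2 CPM of 3.22 and 3.53 in these libraries, against 4.12 to 4.48 in the others and 3.80 to 4.45 in control, so that its lower values against control lie in these 2 libraries. Without them 7473 genes changed in Rg1 plus LPS against LPS and 5659 in Rg1 plus LPS against control. The pattern was not particular to this group. LPS replicates 1 and 4 were the closest pair of theirs (17.45, against 20.75 to 77.94 for its other pairs). On the third principal component, replicates 1 and 4 were positive and the others negative in both groups.

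Some inflammatory genes went with the microglial markers from library to library, which was noticed after the values were seen. In LPS replicates 2 and 3, where the mean log2 CPM of these markers was highest, Il1b stood at 12.7 and 17.9 CPM against 4.74 to 6.13 CPM in the other LPS libraries, and Ccl4 at 19.6 and 26.6 CPM against 8.27 to 10.6 CPM. Control replicate 4, highest in these markers among controls, was also highest in Tnf and Nlrp3 among controls, both at 0.234 CPM. It was highest in oligodendrocyte lineage markers as well (mean log2 CPM 5.607 against 5.1 to 5.207), so it did not stand out in microglial markers alone. Il1b was highest in control replicate 3, with 2 counts against 1 in control replicate 4. Ccl20 did not go this way, with its highest values in LPS replicates 1 and 5 (52.6 and 52.1 CPM). The cell type that carries these transcripts was not resolved.

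Of the tests that follow, those on microglial transcripts, on labels, on LPS action and on the control libraries were chosen after the result was seen, and those on Nlrp2 and on other splits of the libraries before.

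The 97 genes that LPS raised at least 8-fold were all lower in Rg1 plus LPS than in LPS, and there 65 did not differ from control, 28 were below and 4 above. The 17 microglial markers, none of which another list holds, fell less as a list than the 97 genes. Their median log2 fold change was -1.81 (95% bootstrap interval -2.08 to -0.19) against -5.20 (-6.12 to -4.98). The intervals resample genes as if independent, although the estimated correlation of the markers was 0.617, and they cover no spread between libraries. The list median is no clean measure of lost cells, so a loss of microglia as the whole source was not decided. The markers did not move alike: among the abundant ones, looked up after the values were seen, Tmem119 (28.4 CPM in LPS and 36.0 CPM in Rg1 plus LPS) and Cd68 (12.2 and 10.7 CPM) did not pass, while Ctss fell (11.8 and 2.79 CPM). Libraries of the control cultures under a wrong label are argued against by the 5671 genes that differ between Rg1 plus LPS and control. The other splits gave at most 33. Untreated cultures grown or handled apart could differ from control as well, so a wrong label on such cultures is not excluded. Whether Rg1 suppressed the response or LPS failed to act in those cultures cannot be told apart, since no group had Rg1 alone and the 57 genes raised at least 2-fold by LPS and still above control may come from either.

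The 1070 genes that stood apart from control in the same direction in both treated groups hold Nfatc2, Ahrr, Cyp1a1 and Nefm. Chance values of the shared control libraries are argued against as their whole source, since with these libraries parted at least 434 genes still moved the same way, where at most 308.2 were expected. Part of that excess is general overlap of the changed genes, since 263 to 427 moved in opposite ways (at most 322.8 expected), fewer than moved the same way in each of the 20 fits. A part of the LPS response that Rg1 leaves in place may account for them. Control cultures grown or handled apart from the treated ones may give the same 1070 genes, and since the labels give no culture or day the explanations cannot be told apart.

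Nlrp2 had at most 4 counts in any library. Reads shared with other genes and left uncounted are argued against by its transcripts, in which 97.61% of 3554 stretches of 50 bases occur in no other gene's transcripts. A shortened gene model in the authors' counting is argued against by the length behind the deposited FPKM, 3404 bases, which is 100% of the longest annotated transcript. No biological explanation was tested, since the design gives no group with a known Nlrp2 level.

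In each comparison only the real grouping, 1 of 100 splits of the 10 libraries drawn with it included, reached the reported number of changed genes. Chance spread between single libraries is thereby argued against as the source of these numbers. A chance difference between cultures is not excluded, since the 5 libraries of a group may share a culture. The other splits also carry the group difference as spread, which lowers their numbers. The real numbers were 3635, 6976 and 5671 in LPS against control, Rg1 plus LPS against LPS and Rg1 plus LPS against control, and the highest of the other splits were 0, 3407 and 33. The split with 3407 exchanges 1 library of each group. Splits that mixed the groups more evenly also called genes in Rg1 plus LPS against LPS. Rg1 plus LPS replicates 1 and 4 grouped with LPS replicates 1, 4 and 5 gave 1394, and with LPS replicates 1, 2 and 4 gave 585. Both splits place replicates 1 and 4 of both groups together. The median over all splits other than the real one was 0 in each comparison.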
